A study of Mus musculus with 13 samples.

How the data were processed

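RNA of mouse brown adipose tissue was measured in 13 samples. The labels name mice that lacked Stim1 and Stim2 in cells expressing Cre from the adiponectin promoter (KO) and mice with the floxed alleles and no deletion (control). Each genotype was kept at room temperature (RT) or at 4 °C for 6 h (cold). The labels give 4 control cold, 4 KO cold, 2 control RT and 3 KO RT samples, and all 13 carry the same batch label. They do not say that the samples of a group came from separate animals, so p-values measure only the spread between these samples, part of which could be technical.

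Total RNA was extracted and libraries were made with a QuantSeq kit, which reads a tag at the 3′ end of each mRNA, per the labels' protocols. The deposited values are raw counts per Ensembl gene, whole numbers with no scaling. The submitters' processing notes name UMI-tools 1.1.2, Trim Galore 0.6.7, STAR 2.7.10b, HTSeq 0.12.3, edgeR, limma and the build GRCm39, without the role or parameters of each. The annotation was Ensembl release 103, per the deposited table's name. Whether tags were collapsed by molecular identifier and whether strand was used in counting are not given in the sources used here. Counting intervals and bounds therefore cover counting error only, and a gene cannot be told from an overlapping or antisense partner. A 3′ tag does not have to lie in the deleted part of a gene, and cells other than adipocytes keep both genes, so Stim1 and Stim2 tags need not vanish in the knockout.

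The table held 55632 lines, of which 275 repeated an Ensembl identifier with the same counts and were dropped, leaving 55357. For 2558 identifiers the table gave no symbol, and 386 of these took one from a reference gene table. Identifiers without a symbol in either kept their identifier. Those identifiers held 0.00248% to 0.00569% of the counts of a library. Library totals ran from 1570684 to 2016178 counts (median 1800685). The submitters' build differs from that of the reference annotation used here, so only chromosomes as in the deposited table are given. Xist had at most 2 counts and Ddx3y at least 452 in each library, so all libraries came from males and no sex term was fitted. No replicate pair differed by as little as sampling noise: chi-square per degree of freedom was 2.03 to 7.19, and correlations of log2 CPM within groups were 0.938 to 0.975.

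Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (minimum count 10) were kept, 11073 in all, and libraries were scaled by the trimmed mean of M values. All 13 libraries entered 1 quasi-likelihood fit with a coefficient per group, so the groups shared 1 estimate of the spread (common biological coefficient of variation 16.1%). A total of 5 contrasts was tested, each two-sided: KO against control in cold, KO against control at RT, cold against RT in control, cold against RT in KO, and the difference between both cold responses. Adjusted p is the Benjamini-Hochberg value of edgeR's quasi-likelihood test over all tested genes in a contrast, and genes under 0.05 are called changed. Fold changes are log2 with their standard errors. Levels are CPM, counts scaled to a common library size, computed here from the deposited counts and given as mean ± SD over the libraries of a group. Where a group held no count of a gene, the fold is a lower bound from 3 counts over the group, and where it held 1 to 3, the ratio of group totals scaled to library size is given with its exact 95% interval.

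Gene lists for the tissue and treatment, 36 with 814 symbols, were fixed before the data were examined, and 813 symbols matched the table. The 31 lists with at least 5 tested genes were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with its preset correlation of 0.01, adjusted over the lists in a contrast. Camera was run again with a correlation estimated from the data, and fry tested whether members moved 1 way. Member counts adjusted over the list alone used the same test with Benjamini-Hochberg over the list. Genes named in the text followed a rule fixed before the data were examined. Stim1, Stim2 and Ucp1 were always named. The 10 genes with the largest positive and the 10 with the largest negative fold change were named among those past the threshold with mean CPM of at least 5, a proper symbol and groups that did not overlap (the last not for the difference of cold responses). Up to 4 members with the smallest p were named from each list past its threshold or needed to describe the comparison. Which other lists were needed was decided after values were seen, list by list: 9 in KO against control in cold and 4 in cold against RT in control. Where fewer than 5 genes passed, the 10 smallest p were named as not having passed.

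The tests were first run on simulated counts with the means and library sizes of the real samples, 5 draws with 200 changed genes each. In KO against control in cold, on 10699 to 10715 genes, 21.8% of genes changed 1.5-fold, 56.1% of those changed 2-fold and 90.9% of those changed 4-fold were recovered, with 6.03% false calls. At RT the shares were 6.27%, 38.5% and 82.1% (4.32% false, 10690 to 10723 genes). For cold against RT they were 7.16%, 44.8% and 83.9% in control (4.65% false, 10704 to 10741 genes) and 12.8%, 59.7% and 91.2% in KO (5.23% false, 10661 to 10720 genes). For the difference of cold responses they were 2.09%, 17.9% and 73.3% (7.76% false, 10687 to 10743 genes). Camera called a shifted chaperone list and 0 others of the 31. The simulated genes were drawn independently of each other, so false calls that come from correlated genes could not show.

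Alternatives planned in advance were relative log expression scaling, no count filter, a stricter filter (mean CPM 5), DESeq2 1.42.0, limma voom with and without quality weights, the replicate number as a block, a fit of the compared groups alone, a 2-fold threshold and leaving out each library in turn. After the data were seen, fits without the 3 RT libraries with the most skeletal muscle RNA, with a muscle score as covariate, an exact permutation of list scores, pooled markers of 3 further cell types and refits with each count kept at a chance of 50% (5 draws) were added. The fits without the 3 RT libraries leave 1 control RT and 1 KO RT library, so they also lose replication. Other splits of the libraries into groups of the same sizes were refitted, 35 for each of both cold comparisons that allow it. GC content was taken from the last 500 nucleotides of reference transcripts of an earlier mouse build, matched by gene for 99.9% of tested genes. Of the genes picked by the rule for named genes, 2 are withheld for evaluation and not reported here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.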

Results

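Transcripts of mouse brown adipose tissue, the fat depot that burns fuel to make heat, were counted in 13 libraries. Mice lacked Stim1 and Stim2, the sensors of calcium stores in the endoplasmic reticulum (ER), in adipocytes (KO), or carried the floxed alleles without deletion (control). There were 4 control cold, 4 KO cold, 2 control RT and 3 KO RT libraries. Each held between 1570684 and 2016178 counts and detected 15506 to 17061 genes. The first principal component of log2 CPM held 46.2% of the variance and separated cold from RT, and the second held 10.8%. Genes of the mitochondrial genome took 9.43% to 13.4% of counts. Parentheses hold the log2 fold change ± its standard error and q, the adjusted p. A value after "but" is q, or its range, when the named libraries are left out 1 at a time. A further value is the log2 fold change without a library. A ratio is that of the higher over the lower group. For lists, "list alone" counts members past the threshold when adjusted over the list alone.

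Stim1 (ENSMUSG00000030987.6, chromosome 7) was measured at 129, 120.5, 134 and 114 CPM in control cold 1 to 4 and at 81.4, 78.8, 96.8 and 108 CPM in KO cold 1 to 4. At RT it was at 149.9 and 126 CPM in control and at 74.0, 62.0 and 86.1 CPM in KO. Stim2 (ENSMUSG00000039156.20, chromosome 5) was at 31.1, 32.1, 54.5 and 52.9 CPM in control cold, 13.5, 29.7, 26.4 and 22.0 CPM in KO cold, 29.0 and 40.4 CPM in control RT and 22.3, 25.2 and 21.0 CPM in KO RT. Both genes were lower in each KO library than in each control library of the same temperature. Counts per library ran from 108 to 326 for Stim1 and from 22 to 88 for Stim2. In cold, Stim2 fell (-0.88 ± 0.24, q = 0.0382, but 0.0533 to 0.105 without control cold 3 or 4, KO cold 1, 3 or 4 or KO RT 1). Stim1 did not pass (-0.45 ± 0.13, q = 0.0570, but 0.0424 without KO cold 4, called with DESeq2). At RT neither passed, with Stim1 at (-0.90 ± 0.17, q = 0.349, called with DESeq2) and Stim2 at (-0.59 ± 0.31, q = 1). The tags do not have to lie in the deleted part, and tissue cells other than adipocytes keep both genes, so these levels check the labels only in direction. Ucp1 (chromosome 8), which uncouples mitochondria for heat, was at 7504, 9365, 8992 and 9102 CPM in control cold and 6752, 6783, 6905 and 6125 CPM in KO cold. At RT it was at 3187 and 3856 CPM in control and 2436, 3601 and 3513 CPM in KO.

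**Figure D1:**
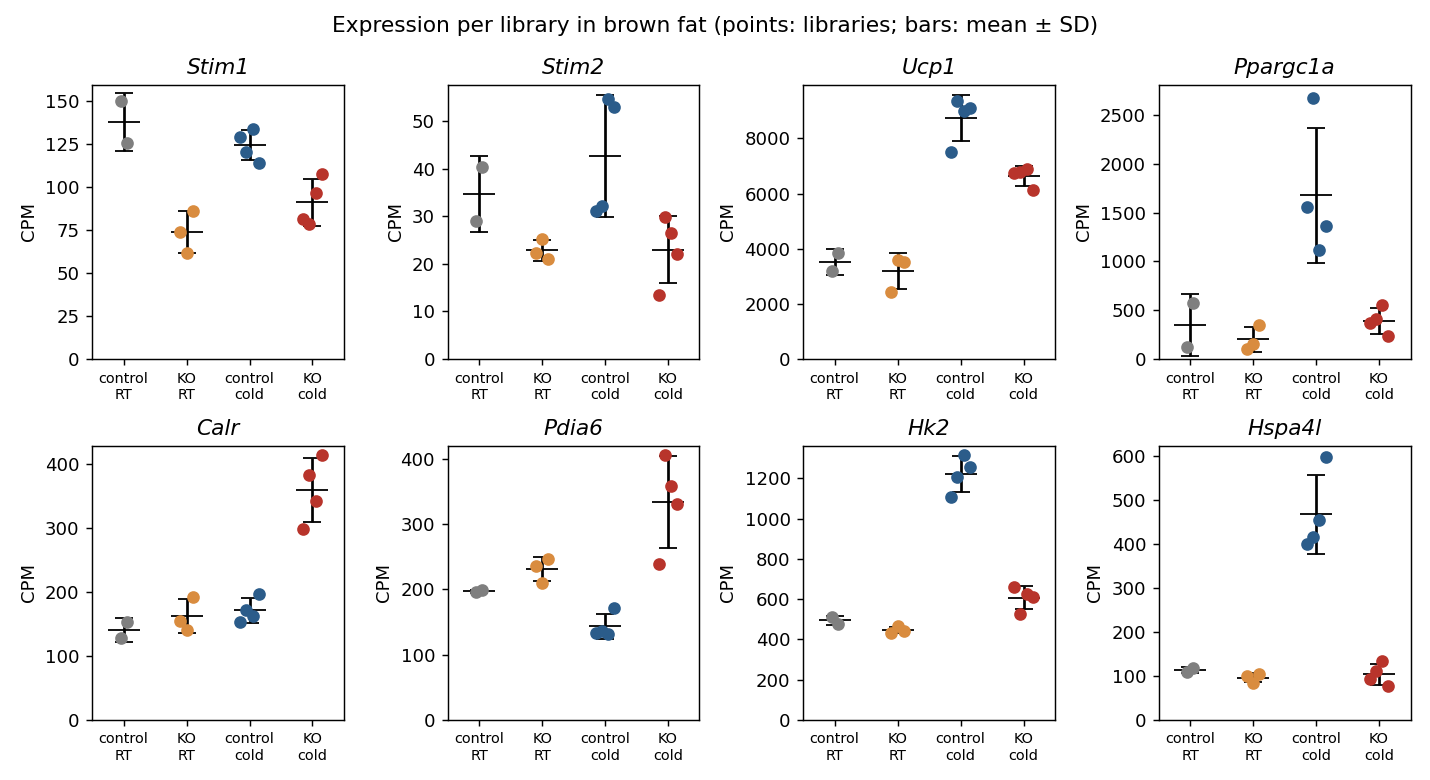
Levels of 8 genes in CPM (vertical axes) in each library of the groups named on the horizontal axes. Points are libraries, bars are mean ± SD, and Stim1, Stim2 and Ucp1 lie lower in every KO cold library than in every control cold library, while Calr and Pdia6 lie higher.

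The comparison of KO with control in cold asks what the loss of both sensors does to the tissue during thermogenic demand. A total of 657 of 11073 genes changed, 270 higher and 387 lower in KO. Pdia6, a protein disulfide isomerase of the ER, rose from 143 ± 19.1 CPM to 333 ± 70.7 CPM (n = 4 each), and Calr, the calcium-binding chaperone of the ER lumen, from 171 ± 18.99 CPM to 360.1 ± 50.4 CPM. Ppargc1a, a coactivator of mitochondrial and thermogenic genes, fell from 1678 ± 690.2 CPM to 389 ± 132 CPM, and Hk2, which phosphorylates glucose, from 1223 ± 89.6 CPM to 606 ± 57.3 CPM. Ucp1 was at 8741 ± 839 CPM in control and 6641 ± 350.2 CPM in KO and did not pass (-0.40 ± 0.12, q = 0.0577, but 0.0294 to 0.0415 without control cold 1 or KO RT 1, called with DESeq2).

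Among genes whose groups did not overlap, the largest rises in KO were those of Aldh3b2 (2.24 ± 0.28, q = 0.000173), Creld2 (2.23 ± 0.31, q = 0.000445), Sdf2l1 (2.22 ± 0.39, q = 0.00282) and Plet1os (1.97 ± 0.36, q = 0.00405). Creld2 and Sdf2l1 encode ER-resident proteins. Plet1os is an antisense gene, and whether its counts were separated from those of its overlapping partner is not given. Trarg1, a regulator of glucose transporter traffic, rose (1.88 ± 0.29, q = 0.000930), as did Retreg1, a receptor for ER-phagy (1.88 ± 0.40, q = 0.0104), and Rwdd3 (1.83 ± 0.31, q = 0.00211). So did Kcnj11, a potassium channel subunit (1.76 ± 0.35, q = 0.00627), Pdia4 (1.75 ± 0.37, q = 0.00992) and Katnal2 (1.72 ± 0.31, q = 0.00366). The largest falls included Fgf9, a growth factor, which was at 42.5 ± 21.4 CPM in control cold and had 1 count over the 4 KO cold libraries (ratio 297, 95% counting interval 52.8 to 11769.6, q = 2.01e-05). Lrrc52 also had 1 count in KO cold (ratio 167, 95% counting interval 29.5 to 6631, q = 2.75e-05). Bdh1, a ketone body dehydrogenase, fell from 27.9 ± 8.50 CPM to 0.989 ± 1.25 CPM (-4.72 ± 0.50, q = 5.10e-05). Dgkg, a diacylglycerol kinase (-4.41 ± 0.51, q = 6.64e-05), Tectb (-3.04 ± 0.45, q = 0.000724) and Gem (-2.73 ± 0.55, q = 0.00721) fell as well. Further falls were those of Cldn1, a tight junction protein (-2.69 ± 0.33, q = 0.000140), Npr3, the natriuretic peptide clearance receptor (-2.55 ± 0.32, q = 0.000140), and Lgr6 (-2.54 ± 0.28, q = 5.10e-05). Rises and falls here compare KO cold with control cold, not with RT. Trarg1 had 21 to 50 counts per library in control cold, 96 to 208 in KO cold and 146 to 295 at RT. Sdf2l1 had 5 to 19, 35 to 67 and 2 to 9. Bdh1 had 0 to 2 counts per library at RT, over both genotypes. The mitochondrial tRNA gene mt-Tc fell (-2.96 ± 0.54, q = 0.00361), and 7 of the 20 tested genes of the mitochondrial chromosome were lower, the others not passing. None of those lower was among the 8 tested members of the list of mitochondrially encoded transcripts.

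Of the list for the unfolded protein response and ER chaperones (24 genes), 14 rose, 0 fell and 10 did not pass (list alone, 18 higher and 0 lower). Its median log2 fold change was 0.87, and 22 of 24 members were positive (camera q = 2.64e-12, 0.853 with an estimated correlation). Fry, which asks whether members move 1 way, also called it (adjusted p = 0.0295), and called none of the other 6 lists. The members with the smallest p were Pdia6 (1.22 ± 0.15, q = 0.000102), Calr (1.07 ± 0.13, q = 0.000140), Creld2 and Dnajb11, a co-chaperone of the ER (0.91 ± 0.16, q = 0.00258). In the heat shock and proteasome list the direction was opposite: of 25 genes, 0 rose, 7 fell and 18 did not pass (list alone, 0 higher and 8 lower), with camera q = 0.000146, 0.853 with an estimated correlation. The falls included the cytosolic chaperones Hsp90ab1 (-0.69 ± 0.14, q = 0.00668), Dnaja1 (-1.45 ± 0.31, q = 0.00992), Hspa8 (-1.24 ± 0.27, q = 0.0107) and Hsph1 (-1.91 ± 0.42, q = 0.0140). Both calls were kept whichever library was left out.

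Genes of the fibroblast and extracellular matrix list were lower in KO cold. Of 24 genes, 0 rose, 3 fell and 21 did not pass (list alone, 0 higher and 3 lower), with camera q = 0.000329, 0.853 with an estimated correlation. The q was 0.0588 without control cold 2. Lox, which crosslinks collagen, fell (-1.51 ± 0.19, q = 0.000140), as did the basement membrane collagens Col4a2 (-0.91 ± 0.15, q = 0.00206) and Col4a1 (-0.83 ± 0.15, q = 0.00323). Col1a2 was at (-0.88 ± 0.34, q = 0.150). For glucose uptake, glycolysis and the TCA cycle, of 39 genes, 1 rose, 6 fell and 32 did not pass (list alone, 1 higher and 10 lower), with camera q = 0.00334, 0.853 with an estimated correlation. The q was 0.106 without control cold 2. Hk2 (-1.01 ± 0.10, q = 1.58e-05) and the phosphofructokinases Pfkl (-1.01 ± 0.14, q = 0.000427) and Pfkp (-0.64 ± 0.14, q = 0.0103) fell. Pdk2, which restrains pyruvate entry into the TCA cycle, rose (0.56 ± 0.11, q = 0.00503). In the immediate early and cAMP target list, of 21 genes, 0 rose, 3 fell and 18 did not pass (list alone, 0 higher and 7 lower), with camera q = 0.00444, 0.853 with an estimated correlation. The q was 0.0584 without control cold 4. Atf3 fell (-2.17 ± 0.50, q = 0.0163, but 0.0515 without KO cold 4), as did Nr4a2 (-2.19 ± 0.52, q = 0.0209, but 0.0519 to 0.0727 without control cold 2 or any KO cold library). Sik1 fell (-1.41 ± 0.37, q = 0.0308, but 0.0579 to 0.0949 without control cold 1, 2 or 4 or KO cold 1, 3 or 4), and Crem was at (-0.84 ± 0.25, q = 0.0527, but 0.00462 to 0.00468 without control RT 1 or 2, called with DESeq2).

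De novo lipogenesis held both directions. Of 27 genes, 1 rose, 3 fell and 23 did not pass (list alone, 1 higher and 5 lower), with camera q = 0.0485, 0.853 with an estimated correlation. The q was 0.0516 to 0.293 without control cold 1, 2 or 3, KO cold 2 or 3 or KO RT 1 or 3. Gpam, which starts triglyceride synthesis, fell (-1.08 ± 0.11, q = 3.43e-05), as did the desaturase Scd1 (-0.74 ± 0.14, q = 0.00628). Elovl5 fell as well (-0.54 ± 0.14, q = 0.0324, but 0.0508 to 0.103 without control cold 1, 2 or 3 or any KO cold library). Aacs rose (1.44 ± 0.35, q = 0.0228, but 0.0581 to 0.0721 without control cold 2, 3 or 4 or KO cold 1 or 4). Of the macrophage and monocyte markers (16 genes), 0 rose, 0 fell and 16 did not pass (list alone, 0 higher and 0 lower). Of the 16, 15 were negative (camera q = 0.0485, 0.853 with an estimated correlation). The q was 0.0516 to 0.664 without control cold 2 or 4, KO cold 1, 3 or 4 or KO RT 1 or 3. The smallest p belonged to Lyz2 (-0.78 ± 0.28, q = 0.111, but 0.0350 without control cold 3) and C1qa (-0.71 ± 0.31, q = 0.201, but 0.0355 without control cold 3). Next came Adgre1 (-0.91 ± 0.49, q = 0.328) and Mrc1 (-0.42 ± 0.23, q = 0.330).

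**Figure D2:**
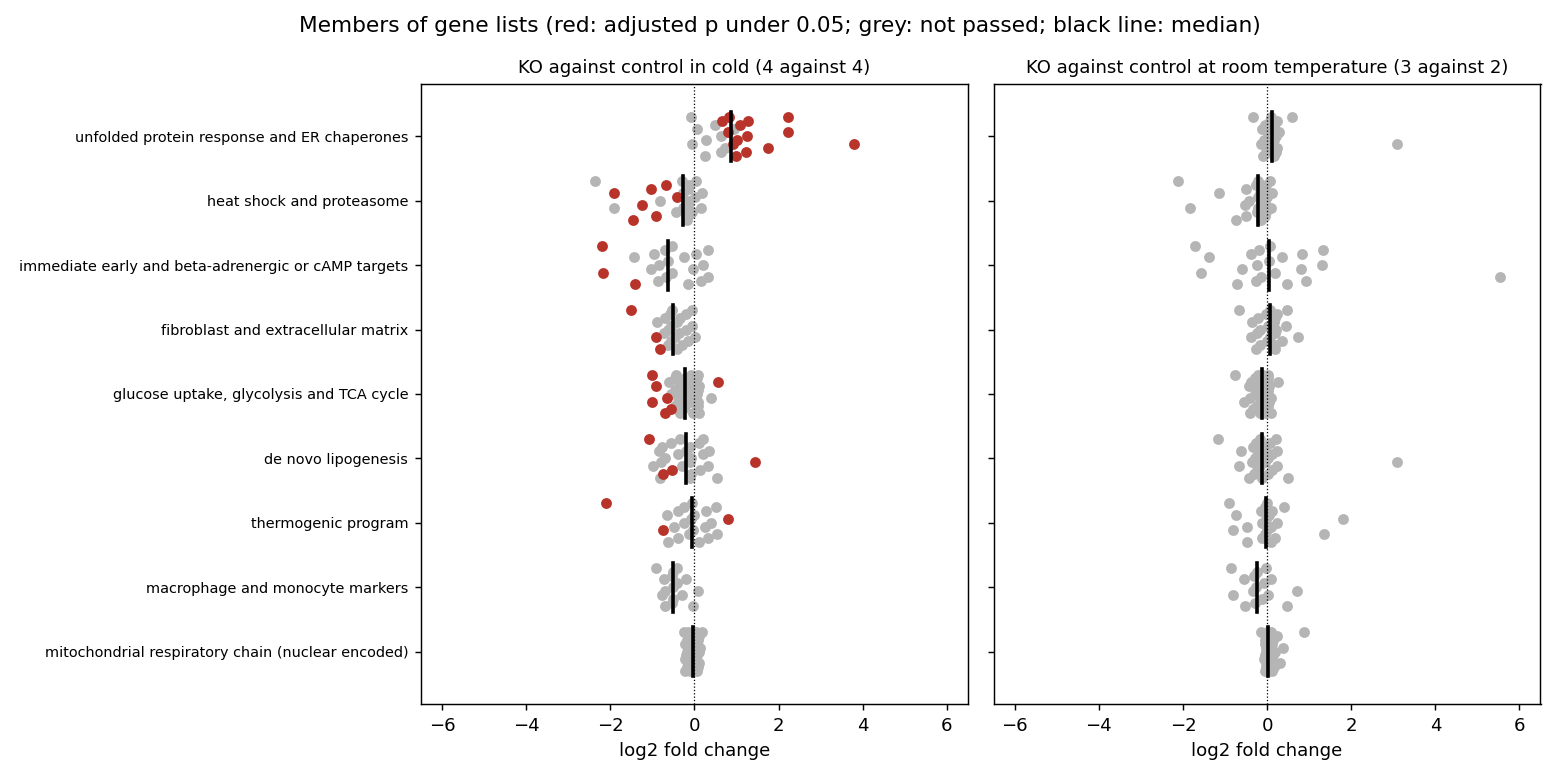
KO against control log2 fold change (horizontal axes) of each measured member of 9 gene lists (vertical axis), in cold and at RT. Points are genes, red past the threshold (adjusted p under 0.05) and grey otherwise, and black lines are medians, 0.87 for ER chaperones in cold.

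The thermogenic program as a whole was not called. Of 22 genes, 1 rose, 2 fell and 19 did not pass (list alone, 2 higher and 5 lower), with camera q = 0.729. Ppargc1a fell (-2.11 ± 0.42, q = 0.00714), as did Gk, glycerol kinase (-0.76 ± 0.18, q = 0.0214, but 0.05 to 0.0624 without control cold 2 or any KO cold library). Ppara, a regulator of fatty acid oxidation, rose (0.81 ± 0.18, q = 0.0145, but 0.0523 without KO cold 2). Of the store-operated calcium entry and ER-plasma membrane contact list (21 genes), 3 rose, 1 fell and 17 did not pass (list alone, 3 higher and 2 lower), with camera q = 0.839. Beside Stim2, the ER calcium channel gene Itpr2 rose (0.49 ± 0.11, q = 0.0171, but 0.0524 without KO cold 4). Gramd1b rose (0.88 ± 0.23, q = 0.0308, but 0.0598 to 0.101 without control cold 1, 2 or 3 or KO cold 2 or 3), as did the calcium channel gene Orai3 (0.59 ± 0.16, q = 0.0382, but 0.0639 to 0.0924 without control cold 2, 3 or 4 or any KO cold library, not called with DESeq2). In the list of calcium cycling, pumps and mitochondrial calcium uptake, of 20 genes, 2 rose, 4 fell and 14 did not pass (list alone, 2 higher and 4 lower), with camera q = 0.804. Beside the rise of Calr, the ER calcium pump gene Atp2a2 fell from 543 ± 55.1 CPM to 337 ± 41.2 CPM (-0.68 ± 0.13, q = 0.00366). Micu3 (-0.57 ± 0.12, q = 0.0128) and Mcur1 (-0.46 ± 0.11, q = 0.0204, but 0.0505 to 0.0708 without control cold 2 or KO cold 1, 2 or 3), both of mitochondrial calcium uptake, fell too. Of the calcineurin-NFAT and CREB calcium targets (16 genes), 0 rose, 1 fell and 15 did not pass (list alone, 0 higher and 1 lower), with camera q = 0.855. Rcan1, a target and inhibitor of calcineurin, fell (-0.51 ± 0.14, q = 0.0446, but 0.0527 to 0.119 without any library but KO cold 2, not called with DESeq2). Nfatc1 was at (0.85 ± 0.31, q = 0.115), Nfatc2 at (-1.10 ± 0.52, q = 0.249) and Ppp3cb at (-0.19 ± 0.09, q = 0.273).

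Lipid handling genes moved in both directions. Of the lipolysis and lipid droplet list (19 genes), 2 rose, 1 fell and 16 did not pass (list alone, 5 higher and 1 lower), with camera q = 0.164. Abhd5, which activates the triglyceride lipase, fell (-0.93 ± 0.16, q = 0.00211). Lipe, hormone-sensitive lipase (0.60 ± 0.11, q = 0.00472), and the droplet coat gene Plin5 (0.46 ± 0.11, q = 0.0241, but 0.0596 to 0.0837 without control cold 1 or 4 or KO cold 2 or 3) rose. Cideb was at (1.29 ± 0.44, q = 0.0984, but 0.0350 without KO cold 4). For lipid uptake, of 17 genes, 3 rose, 0 fell and 14 did not pass (list alone, 5 higher and 3 lower), with camera q = 0.779. The fatty acid transporter gene Slc27a1 rose (1.09 ± 0.24, q = 0.0144), as did Angptl4, an inhibitor of lipoprotein lipase (0.89 ± 0.20, q = 0.0170, but 0.0510 to 0.0542 without control cold 2 or KO cold 4). Scarb1 rose too (0.79 ± 0.19, q = 0.0226, but 0.0504 to 0.0711 without control cold 1, 2 or 4 or KO cold 2, 3 or 4). Lpl, lipoprotein lipase, was at (-0.30 ± 0.09, q = 0.0507, but 0.0270 to 0.0461 without control cold 1 or control RT 1 or 2, called with DESeq2, called with relative log expression scaling). In the adipocyte identity list, of 21 genes, 2 rose, 3 fell and 16 did not pass (list alone, 4 higher and 3 lower), with camera q = 0.839. The transcription factor gene Ebf1 (-1.28 ± 0.12, q = 1.00e-05) and Cav1, of caveolae (-1.18 ± 0.11, q = 1.82e-05), fell. Cfd, adipsin, rose (0.55 ± 0.13, q = 0.0186, but 0.0508 to 0.0631 without control cold 3 or KO cold 1 or 4). For creatine and other futile cycles, of 13 genes, 1 rose, 1 fell and 11 did not pass (list alone, 1 higher and 1 lower), with camera q = 0.855. Bcat2, of branched-chain amino acid breakdown, rose (1.07 ± 0.14, q = 0.000292). Slc25a44, a mitochondrial carrier of these amino acids, fell (-0.39 ± 0.11, q = 0.0461, but 0.0523 to 0.125 without any library but control cold 4). Slc6a8 was at (-0.73 ± 0.27, q = 0.125) and Alpl at (0.46 ± 0.33, q = 0.482). Of the secreted factors of brown fat (14 genes), 2 rose, 1 fell and 11 did not pass (list alone, 2 higher and 1 lower), with camera q = 0.647. Igf1 fell (-1.09 ± 0.24, q = 0.0125) and Fst, follistatin, rose (1.15 ± 0.27, q = 0.0202, but 0.0523 to 0.0603 without control cold 2 or KO cold 4). Ptgds was at (-1.18 ± 0.48, q = 0.171).

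In 8 further lists edgeR passed 0 members in cold: nuclear-encoded respiratory chain (45 genes), mitochondrially encoded transcripts (8, of which 1 was lower in the list alone), cholesterol synthesis (20), type I interferon response (13), endothelial markers (20), erythrocyte markers (6), cytosolic ribosomal proteins (30) and the core clock (19, of which 1 was higher and 3 lower in the list alone). Fatty acid oxidation had 1 rise and 1 fall among 29 genes, and the integrated and mitochondrial stress response 1 rise among 28 (list alone, 3 higher and 1 lower). Of markers of other cells, 2 of 13 smooth muscle and pericyte genes, 1 of 19 skeletal muscle, 1 of 8 Schwann cell and nerve (2 in the list alone) and 1 of 9 white adipocyte genes fell. Of 15 hypoxia and angiogenesis genes 1 fell (list alone, 1 higher and 2 lower). Camera adjusted p of these lists lay between 0.0922 and 0.973. With fewer than 5 tested genes, 5 lists were not tested: T, B and NK lymphocytes (3 of 23 symbols), granulocytes and mast cells (3 of 15), inflammatory and chemokine genes (4 of 23), mesothelium and epithelium (1 of 11) and cell cycle (4 of 24). Median, mean and camera direction differed in sign in 8 of 31 lists, none of them called: store-operated calcium entry, calcium cycling, fatty acid oxidation, lipid uptake, integrated stress, creatine, adipocyte identity and skeletal muscle.

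The 657 calls held 232 genes changed 2-fold or more (109 higher, 123 lower), and 2224 genes had an unadjusted p under 0.05. Groups did not overlap for 1418 genes (12.8%, against 2.86% by chance), 583 of them called, and the groups of every gene named here as changed in KO cold were apart except for Ppara and Scarb1. The count was 425, 417, 400 and 392 without KO cold 1, 2, 3 and 4. Of 31 lists 7 were called, 4 without control cold 2 and 0 with an estimated correlation, and other splits of the 8 cold libraries called up to 13, so chance is not excluded for the number of lists.

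At RT, which asks whether the knockout alters the tissue before cold, edgeR called 0 of 11073 genes between 3 KO and 2 control libraries. An unadjusted p under 0.05 was met by 346 (816 without control RT 1, with 3 genes called, and 567 without the 3 muscle-rich libraries, with 0 called), and the smallest adjusted p was 0.349. Stim1 and Sdhb had the smallest p. Sdhb, a subunit of succinate dehydrogenase, was at 515 ± 125 CPM in control and 945 ± 89.9 CPM in KO (0.88 ± 0.16, q = 0.349, called with DESeq2). DESeq2 called 3 genes, Sdhb, Stim1 and Lgr6, and voom with and without quality weights 0. The other genes with the smallest p, none past the threshold, were Lgr6 (-1.72 ± 0.36, q = 0.501, called with DESeq2), Bcat2 (0.80 ± 0.18, q = 0.633) and Eif4a2 (0.59 ± 0.13, q = 0.633). They also included Cdc25a (1.04 ± 0.24, q = 0.633), Rnf152 (-0.76 ± 0.17, q = 0.633) and Fosl2 (-1.38 ± 0.34, q = 0.793, but 0.0209 without control RT 1). Lgals3bp was at (-0.87 ± 0.21, q = 0.793) and Elovl3 at (1.36 ± 0.33, q = 0.793). Ucp1 was at (-0.15 ± 0.15, q = 1, 0.00 without control RT 2, 0.01 without KO RT 1).

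Camera called 4 lists at RT, in each of which 0 members passed, in the list alone too. Type I interferon response genes were lower, 12 of 13 negative (camera q = 0.000528, 0.701 with an estimated correlation). Bst2 was at (-0.73 ± 0.32, q = 1), Ifit1 at (-1.11 ± 0.49, q = 1), Xaf1 at (-0.91 ± 0.44, q = 1) and Rtp4 at (-0.48 ± 0.24, q = 1). Glucose uptake, glycolysis and the TCA cycle were lower, 28 of 39 negative (camera q = 0.00668, 0.915 with an estimated correlation). The q was 0.152 to 0.806 without control RT 1 or KO RT 2. Members with the smallest p were Pfkl (-0.55 ± 0.18, q = 1), Hk1 (-0.77 ± 0.29, q = 1), Pkm (-0.41 ± 0.17, q = 1) and Gys2 (-0.40 ± 0.20, q = 1). Heat shock and proteasome genes were lower, 21 of 25 negative (camera q = 0.0142, 0.915 with an estimated correlation). The q was 0.0882 to 0.881 without control RT 2 or KO RT 1 or 2. Without control RT 2 the list turned. Psmc4 was at (-0.53 ± 0.21, q = 1), Hspa1a at (-2.12 ± 0.93, q = 1, 1.07 without control RT 2) and Hspa1b at (-1.82 ± 0.88, q = 1, 1.07 without control RT 2). Hsph1 was at (-1.14 ± 0.56, q = 1, 0.70 without control RT 2). Hspa1a and Hspa1b are near-identical copies, so their split of counts is uncertain, as is that of Hbb-bs and Hbb-bt. Erythrocyte markers were higher, 6 of 6 positive (camera q = 0.0261, 0.915 with an estimated correlation). The q was 0.367 to 0.830 without control RT 1 or KO RT 1, and the list turned without control RT 1. Alas2 was at (0.89 ± 0.52, q = 1), Hbb-bt at (0.53 ± 0.40, q = 1) and Hbb-bs at (0.37 ± 0.35, q = 1, -0.09 without control RT 1).

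Skeletal muscle transcripts differed between the RT libraries. The mean log2 CPM of 19 muscle genes was 6.88 and 1.87 in control RT 1 and 2 and 6.17, 5.77 and 2.99 in KO RT 1, 2 and 3, against 1.05 to 4.20 in cold. At RT 0 of 19 muscle genes passed, with 18 of 19 negative in KO while camera pointed up (adjusted p = 0.460), with a median of -0.52. Besides skeletal muscle, median, mean and camera differed in sign in 9 lists, none called: thermogenic program, calcineurin-NFAT, mitochondrially encoded transcripts, lipolysis, creatine, adipocyte identity, smooth muscle, extracellular matrix and core clock. Fry called a different list, store-operated calcium entry, lower (adjusted p = 0.0326). The deleted genes Stim1 and Stim2 are themselves members of that list. Groups did not overlap for 1842 genes (16.6%, against 20% by chance). Without control RT 1, 3 genes and 9 lists were called, and lists numbered 7 without control RT 2 or KO RT 1 and 2 without KO RT 2.

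**Figure D3:**
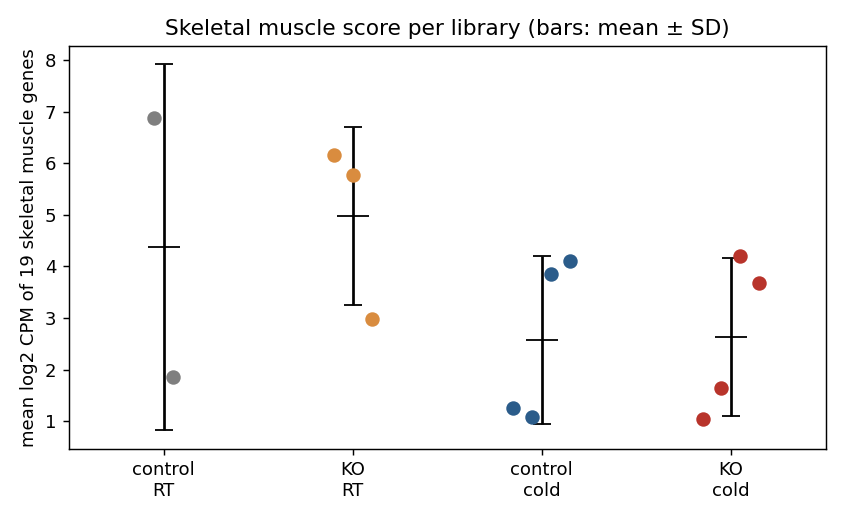
Mean log2 CPM of 19 skeletal muscle genes (vertical axis) in each of the 13 libraries (points), by group (horizontal axis). Control RT 1, KO RT 1 and KO RT 2, at 6.88, 6.17 and 5.77, lie above all cold libraries, the highest of which is at 4.20.

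The comparison of cold with RT in control mice gives the response to 6 h at 4 °C with both genes intact. Cold changed 2793 genes, 1401 higher and 1392 lower. Ucp1 rose from 3521 ± 474 CPM (n = 2) to 8741 ± 839 CPM (n = 4; 1.31 ± 0.15, q = 3.26e-05). Elovl3, which elongates fatty acids, rose from 35.6 ± 9.46 CPM to 409 ± 84.3 CPM (3.51 ± 0.34, q = 5.36e-06). Srebf1 (-2.38 ± 0.28, q = 3.59e-05) and Thrsp (-2.36 ± 0.30, q = 5.93e-05), of lipogenesis, fell.

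Fgf21, a secreted metabolic hormone, had 0 counts at RT and was higher in cold (at least 45.4-fold, q = 0.00919, but 0.0791 without control RT 1). Bdh1 (at least 35.4-fold, q = 5.25e-05) and the dopamine receptor gene Drd1 (at least 17.6-fold, q = 0.00157) also had 0 counts at RT. Rises from 1 to 3 counts were those of Dgkg (ratio 85.3, 95% counting interval 15.1 to 3391, q = 8.09e-05) and Smim41 (ratio 41.4, 95% counting interval 11.3 to 346, q = 0.000186). Ttpa, which binds vitamin E (ratio 41.4, 95% counting interval 11.3 to 346, q = 0.00213), and Chac1, which degrades glutathione (ratio 31.2, 95% counting interval 10.5 to 153, q = 0.00713, but 0.0732 without control RT 1), rose likewise. So did Lrrc52 (ratio 30.02, 95% counting interval 10.1 to 147, q = 0.000165). Acot5, an acyl-CoA thioesterase with close copies in Acot1 and Acot2, rose (5.35 ± 0.69, q = 6.92e-05). Gdf15, a stress-induced cytokine, rose too (4.99 ± 1.54, q = 0.0264, but 0.0651 to 0.159 without control cold 4 or control RT 1 or 2). The largest falls were those of Hcar1, the lactate receptor (-4.85 ± 0.49, q = 7.17e-06), Angpt1 (-3.66 ± 0.30, q = 1.83e-06) and Cenpa (-3.59 ± 0.40, q = 1.84e-05). Next were the chloride channel gene Ano1 (-3.39 ± 0.42, q = 4.59e-05) and Mfsd12 (-3.14 ± 0.37, q = 3.59e-05). Tspan18 (-3.11 ± 0.32, q = 1.03e-05), Rcor2 (-3.10 ± 0.50, q = 0.000384), P2rx5 (-3.08 ± 0.27, q = 3.06e-06), Nav2 (-3.06 ± 0.33, q = 1.53e-05) and Esr1, the estrogen receptor (-3.05 ± 0.29, q = 5.36e-06), followed.

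Of the thermogenic program (22 genes), 10 rose, 2 fell and 10 did not pass (list alone, 10 higher and 3 lower), with camera q = 0.00433, 0.802 with an estimated correlation. Gk (2.06 ± 0.25, q = 3.82e-05) and Kcnk3 (0.99 ± 0.15, q = 0.000276) were among the rises. Of the immediate early and cAMP targets (21 genes), 10 rose, 0 fell and 11 did not pass (list alone, 14 higher and 0 lower), with camera q = 1.31e-05, 0.802 with an estimated correlation. Maff (3.75 ± 0.32, q = 3.06e-06), Pde4d (1.49 ± 0.26, q = 0.000647), Gadd45g (1.93 ± 0.36, q = 0.00111) and Dusp1 (2.16 ± 0.41, q = 0.00146) rose. For the integrated and mitochondrial stress response, of 28 genes, 18 rose, 0 fell and 10 did not pass (list alone, 19 higher and 1 lower), with camera q = 1.31e-05, 0.802 with an estimated correlation. Hspe1 (1.14 ± 0.16, q = 0.000113) and Atf5 (1.26 ± 0.24, q = 0.00156) rose, as did Cebpb (0.87 ± 0.17, q = 0.00195, but 0.0645 without control RT 1) and Cth (3.56 ± 0.74, q = 0.00258). Heat shock and proteasome genes were higher. Of 25 genes, 10 rose, 0 fell and 15 did not pass (list alone, 11 higher and 0 lower), with camera q = 0.000687, 0.802 with an estimated correlation. Among them were Psmd12 (0.79 ± 0.15, q = 0.00130), Hsp90aa1 (1.59 ± 0.30, q = 0.00136, 2.39 without control RT 2) and Hspa8 (1.81 ± 0.35, q = 0.00167, 1.20 without control RT 1, 2.81 without control RT 2). The type I interferon list was lower. Of 13 genes, 0 rose, 6 fell and 7 did not pass (list alone, 0 higher and 10 lower), with camera q = 0.00126, 0.802 with an estimated correlation. The falls included the antiviral gene Rsad2 (-1.63 ± 0.28, q = 0.000710) and Rtp4 (-1.36 ± 0.25, q = 0.00108). Further falls were Irf9 (-0.97 ± 0.26, q = 0.0126, but 0.0938 without control RT 1) and Ifi27l2a (-0.87 ± 0.25, q = 0.0198, but 0.0512 to 0.182 without control cold 1 or control RT 2).

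De novo lipogenesis was lower. Of 27 genes, 2 rose, 11 fell and 14 did not pass (list alone, 2 higher and 12 lower), with camera q = 0.0108, 0.802 with an estimated correlation. The q was 0.247 without control RT 1. Scd2 fell (-1.76 ± 0.31, q = 0.000800, but 0.0739 without control RT 1, -0.99 without control RT 1) and Gpam rose (1.1 ± 0.14, q = 7.35e-05). Of the nuclear-encoded respiratory chain (45 genes), 5 rose, 0 fell and 40 did not pass (list alone, 2 higher and 0 lower), with camera q = 0.00712, 0.802 with an estimated correlation. The q was 0.117 to 0.136 without control cold 2 or control RT 2. Sdhb (0.93 ± 0.15, q = 0.000478) and Etfdh (0.45 ± 0.12, q = 0.0127, but 0.0720 to 0.0753 without control RT 1 or 2) rose. Atp5b rose as well (0.31 ± 0.09, q = 0.0244, but 0.0927 to 0.129 without control RT 1 or 2). Of mitochondrially encoded transcripts (8 genes), 6 rose, 0 fell and 2 did not pass (list alone, 6 higher and 0 lower), with camera q = 0.0108, 0.802 with an estimated correlation. The q was 0.107 without control RT 1. Examples are mt-Co1 (0.88 ± 0.17, q = 0.00156, but 0.0502 without control RT 1) and mt-Nd5 (0.61 ± 0.14, q = 0.00426, but 0.0906 without control RT 1). Of cytosolic ribosomal proteins (30 genes), 4 rose, 0 fell and 26 did not pass (list alone, 4 higher and 0 lower), with camera q = 0.00479, 0.802 with an estimated correlation. The q was 0.229 without control RT 1. Examples are Rpl37 (0.45 ± 0.13, q = 0.0225, but 0.344 without control RT 1, 0.26 without control RT 1, 0.67 without control RT 2). Rps6 rose too (0.62 ± 0.19, q = 0.0241, but 0.0696 to 0.163 without control RT 1 or 2). Glucose genes were not called as a list: of 39 genes, 8 rose, 3 fell and 28 did not pass (list alone, 8 higher and 3 lower), with camera q = 0.0744. Hk2 (1.31 ± 0.12, q = 5.36e-06), Pfkp (1.96 ± 0.19, q = 5.36e-06) and Hk1 (1.15 ± 0.25, q = 0.00385) rose. Pfkm, the muscle-type enzyme, fell (-1.09 ± 0.25, q = 0.00494, but 0.241 without control RT 1, -0.58 without control RT 1). Of the ER chaperone list (24 genes), 4 rose, 0 fell and 20 did not pass (list alone, 4 higher and 0 lower), with camera q = 0.330. Its median was 0.26, or 0.14 with a member at its bound.

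Of skeletal muscle markers (19 genes), 0 rose, 11 fell and 8 did not pass (list alone, 1 higher and 18 lower), with camera q = 0.102. Myl1 fell (-1.55 ± 0.29, q = 0.00113, but 0.0983 without control RT 1, -0.79 without control RT 1), as did Mylpf (-4.38 ± 1.19, q = 0.0133, not called with DESeq2). Eno3 fell (-2.96 ± 0.91, q = 0.0255, but 0.0598 to 0.0673 without control cold 1 or 2, not called with DESeq2, 2.16 without control RT 1), as did Actn3 (-3.78 ± 1.17, q = 0.0265, but 0.0614 to 0.0673 without control cold 1 or 2, not called with DESeq2). Without control RT 1, the library with the highest muscle score, the falls of the last 3 were not seen (q = 0.474, 0.456 and 0.510). Control RT 2, the library then left at RT, had 0 counts of Mylpf and Actn3 and 2 of Eno3, near the floor of detection. The groups of Mylpf, Eno3, Actn3 and Ifi27l2a overlapped, and those of the other genes named as changed in control did not. Of the 2793 genes, 1381 changed 2-fold or more (508 higher, 873 lower), and 4473 genes had groups apart (40.4%, against 13.3% by chance). The count was 1067 without control RT 1 and 870 without control RT 1, KO RT 1 and KO RT 2, the muscle-rich libraries, and a fit of both control groups alone gave 1685. Of the 9 lists that camera called, fry called 5, and 1 other, store-operated calcium entry. Median, mean and camera differed in sign in 3 lists, none called: both calcium lists and the extracellular matrix.

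In KO mice, cold against RT changed 2090 genes, 1044 higher and 1046 lower. Ucp1 rose from 3183 ± 649 CPM (n = 3) to 6641 ± 350.2 CPM (n = 4; 1.06 ± 0.13, q = 5.36e-05). Elovl3 rose from 92.5 ± 43.1 CPM to 598 ± 104 CPM (2.69 ± 0.26, q = 6.30e-06). Manf, an ER stress-induced secreted protein, rose from 32.4 ± 6.51 CPM to 156 ± 51.0 CPM (2.27 ± 0.27, q = 3.65e-05). Stim1 (0.30 ± 0.15, q = 0.172) and Stim2 (0.02 ± 0.27, q = 0.976, -0.13 without KO cold 2, -0.06 without KO cold 3, 0.00 without KO RT 1, -0.03 without KO RT 3) did not pass. In control they were at (-0.15 ± 0.16, q = 0.521) and (0.30 ± 0.28, q = 0.457).

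The largest rises started from 1 or 2 counts at RT. They were those of Smim41 (ratio 221, 95% counting interval 39.3 to 8757, q = 5.23e-06), Fgf21 (ratio 131, 95% counting interval 23.3 to 5223, q = 0.0124, but 0.0550 without KO RT 1) and Muc2 (ratio 34.4, 95% counting interval 9.25 to 289, q = 0.000757). Others were Cyp2b10 (4.22 ± 0.38, q = 3.08e-06), the lysolipid transporter gene Mfsd2a (4.14 ± 0.76, q = 0.00120) and Acot5 (4.06 ± 0.54, q = 0.000102). Chac1 (3.91 ± 0.85, q = 0.00419) and Trib3 (3.83 ± 0.64, q = 0.000618) rose. So did the amino acid transporter genes Slc7a8 (3.65 ± 0.36, q = 7.98e-06) and Slc7a5 (3.64 ± 1.02, q = 0.0189, but 0.0610 to 0.0706 without KO RT 1 or 3). The largest falls were those of Hcar1 (-5.45 ± 0.47, q = 2.59e-06) and the muscle gene Tcap (-3.61 ± 1.21, q = 0.0464, but 0.0508 to 0.322 without control cold 1 or 3, any KO cold library or KO RT 1 or 2, not called with DESeq2, -2.33 without KO RT 1). Next were Angpt1 (-3.48 ± 0.25, q = 4.80e-07), Anxa8 (-3.44 ± 0.43, q = 6.11e-05) and the peptide hormone gene Apln (-3.26 ± 0.50, q = 0.000313). Klhdc7a (-3.25 ± 0.36, q = 2.06e-05), Coq8a (-3.13 ± 0.35, q = 2.38e-05), Irs3 (-2.95 ± 0.62, q = 0.00314), Hcar2 (-2.83 ± 0.49, q = 0.000761) and Esr1 (-2.79 ± 0.25, q = 3.08e-06) followed.

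Camera called 15 lists in KO, 0 with an estimated correlation, and fry called 8, 7 of them among the 15. For the integrated stress response, of 28 genes, 20 rose, 0 fell and 8 did not pass (list alone, 21 higher and 0 lower), with camera q = 2.92e-10, 0.545 with an estimated correlation. Its smallest p were those of Atf5 (1.62 ± 0.21, q = 0.000100), Ddit4 (3.03 ± 0.45, q = 0.000262) and Slc3a2 (2.54 ± 0.40, q = 0.000412). Of the ER chaperone list (24 genes), 16 rose, 0 fell and 8 did not pass (list alone, 17 higher and 0 lower), with camera q = 3.60e-09, 0.545 with an estimated correlation. Beside Manf, the rises included Calr (1.15 ± 0.15, q = 6.65e-05), Hsp90b1 (1.32 ± 0.20, q = 0.000259) and Sdf2l1 (3.11 ± 0.47, q = 0.000277). De novo lipogenesis was lower. Of 27 genes, 0 rose, 13 fell and 14 did not pass (list alone, 2 higher and 14 lower), with camera q = 5.09e-05, 0.545 with an estimated correlation. Examples are Srebf1 (-2.24 ± 0.25, q = 2.37e-05), Thrsp (-2.10 ± 0.28, q = 9.72e-05), Pnpla3 (-1.86 ± 0.33, q = 0.00108) and Dgat2 (-1.66 ± 0.33, q = 0.00225). Of the thermogenic program (22 genes), 10 rose, 0 fell and 12 did not pass (list alone, 10 higher and 0 lower), with camera q = 0.000188, 0.545 with an estimated correlation. Examples are Gk (2.20 ± 0.21, q = 6.30e-06) and Fabp3 (1.26 ± 0.19, q = 0.000259). Of lipolysis and lipid droplet genes (19 genes), 6 rose, 0 fell and 13 did not pass (list alone, 7 higher and 0 lower), with camera q = 0.00279, 0.545 with an estimated correlation. Examples are Fitm2 (0.98 ± 0.14, q = 0.000192), Plin5 (0.78 ± 0.12, q = 0.000434) and Plin2 (1.14 ± 0.23, q = 0.00218). Of immediate early genes (21 genes), 6 rose, 1 fell and 14 did not pass (list alone, 6 higher and 2 lower), with camera q = 0.00530, 0.545 with an estimated correlation. Examples are Maff (3.60 ± 0.29, q = 1.59e-06), Pde4d (1.47 ± 0.22, q = 0.000265) and Fosl2 (1.77 ± 0.29, q = 0.000568). Of heat shock and proteasome genes (25 genes), 8 rose, 0 fell and 17 did not pass (list alone, 12 higher and 0 lower), with camera q = 0.00721, 0.545 with an estimated correlation. Examples are the proteasome genes Psmc4 (1.16 ± 0.18, q = 0.000327) and Psmd11 (0.57 ± 0.13, q = 0.00461).

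Skeletal muscle markers were lower in cold: of 19 genes, 0 rose, 4 fell and 15 did not pass (list alone, 0 higher and 14 lower), with camera q = 0.00279, 0.587 with an estimated correlation. Myl1 fell (-1.26 ± 0.26, q = 0.00305), as did Myh2 (ratio 31.6, 95% counting interval 8.30 to 268, q = 0.0328, but 0.0539 to 0.0821 without any KO cold library, not called with DESeq2). Mylpf fell too (-3.26 ± 1.06, q = 0.0406, but 0.0501 to 0.189 without control cold 1, any KO cold library or KO RT 1 or 2, not called with DESeq2). The groups of Myh2 and Mylpf overlapped, and those of the other genes named as changed in KO did not. Fatty acid oxidation was higher. Of 29 genes, 10 rose, 2 fell and 17 did not pass (list alone, 10 higher and 2 lower), with camera q = 0.0221, 0.545 with an estimated correlation. The q was 0.0638 to 0.0787 without KO RT 1 or 2. Acaa1b fell (-1.31 ± 0.19, q = 0.000263). The near copies Acot1 (1.84 ± 0.39, q = 0.00315, 2.78 without KO RT 3) and Acot2 (1.48 ± 0.31, q = 0.00334) rose. Interferon genes were lower. Of 13 genes, 0 rose, 2 fell and 11 did not pass (list alone, 0 higher and 2 lower), with camera q = 0.0292, 0.545 with an estimated correlation. The q was 0.0638 to 0.0856 without KO cold 1 or KO RT 1 or 2. Rsad2 (-1.38 ± 0.26, q = 0.00139) and Rtp4 (-0.95 ± 0.23, q = 0.00877) fell. Endothelial markers were higher. Of 20 genes, 5 rose, 0 fell and 15 did not pass (list alone, 5 higher and 0 lower), with camera q = 0.0334, 0.545 with an estimated correlation. The q was 0.0588 to 0.0893 without KO cold 2 or KO RT 1 or 3. Examples are Gpihbp1 (1.16 ± 0.18, q = 0.000329) and Sox17 (1.96 ± 0.33, q = 0.000577). Adipocyte identity was lower. Of 21 genes, 1 rose, 5 fell and 15 did not pass (list alone, 1 higher and 6 lower), with camera q = 0.0363, 0.545 with an estimated correlation. The q was 0.0507 to 0.0864 without KO cold 2 or 3 or KO RT 1 or 2. Car3 (-0.89 ± 0.10, q = 2.35e-05) and Cebpa (-1.23 ± 0.25, q = 0.00262) fell and Klf15 rose (1.24 ± 0.23, q = 0.00150).

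Of mitochondrially encoded transcripts (8 genes), 2 rose, 0 fell and 6 did not pass (list alone, 2 higher and 0 lower), with camera q = 0.0392, 0.545 with an estimated correlation. The q was 0.0507 to 0.114 without KO cold 1, 3 or 4 or KO RT 1 or 2. The rises were mt-Co1 (0.63 ± 0.15, q = 0.00655) and mt-Nd5 (0.41 ± 0.12, q = 0.0246, but 0.0514 to 0.119 without KO cold 1 or 3 or KO RT 1 or 2). Extracellular matrix genes were lower in cold: of 24 genes, 0 rose, 8 fell and 16 did not pass (list alone, 0 higher and 9 lower), with camera q = 0.0392, 0.602 with an estimated correlation. The q was 0.0615 to 0.336 without control cold 4, KO cold 1 or 4, control RT 1 or 2 or KO RT 1. Examples are Col15a1 (-1.62 ± 0.23, q = 0.000211) and Col6a3 (-1.15 ± 0.26, q = 0.00566, but 0.0573 without KO RT 1). Of ribosomal proteins (30 genes), 1 rose, 0 fell and 29 did not pass (list alone, 0 higher and 0 lower), with camera q = 0.0184, 0.587 with an estimated correlation. The q was 0.0638 without KO RT 2. The rise was that of Rps6 (0.49 ± 0.16, q = 0.0428, but 0.0742 to 0.188 without KO cold 1, 3 or 4 or KO RT 2 or 3, not called with DESeq2, 0.33 without KO RT 3). Of the 2090 genes, 931 changed 2-fold or more (375 higher, 556 lower), and 3571 genes had groups apart (32.2%, against 5.71% by chance). The muscle score was 6.17, 5.77 and 2.99 in KO RT and 1.05 to 4.20 in KO cold. Without the 3 muscle-rich libraries only KO RT 3 is left in its group, so lost replication also lowers the count. Without KO RT 1 the counts were 1219 genes and 9 lists, without the 3 muscle-rich libraries 452 genes, and with the muscle score as covariate 1304. The calcium cycling list differed in sign, with a median of -0.01 and camera up, and was not called.

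Both cold responses ran largely in parallel, from comparisons that share no library. Across genes, which are not independent replicates, their log2 fold changes correlated at r = 0.79. A total of 1434 genes was called in both, each in the same direction (719 higher and 715 lower, against 132 and 131 for independent lists). Another 1359 were called in control alone and 656 in KO alone, which does not show that they differ. The KO effect in cold and at RT correlated at r = 0.17 over all genes and 0.44 over the 657, of which 462 had the same sign at RT (70.3%, against 54.3% of all genes). The median size of these effects was 0.83 in cold and 0.12, signed by the direction in cold, at RT.

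**Figure D4:**
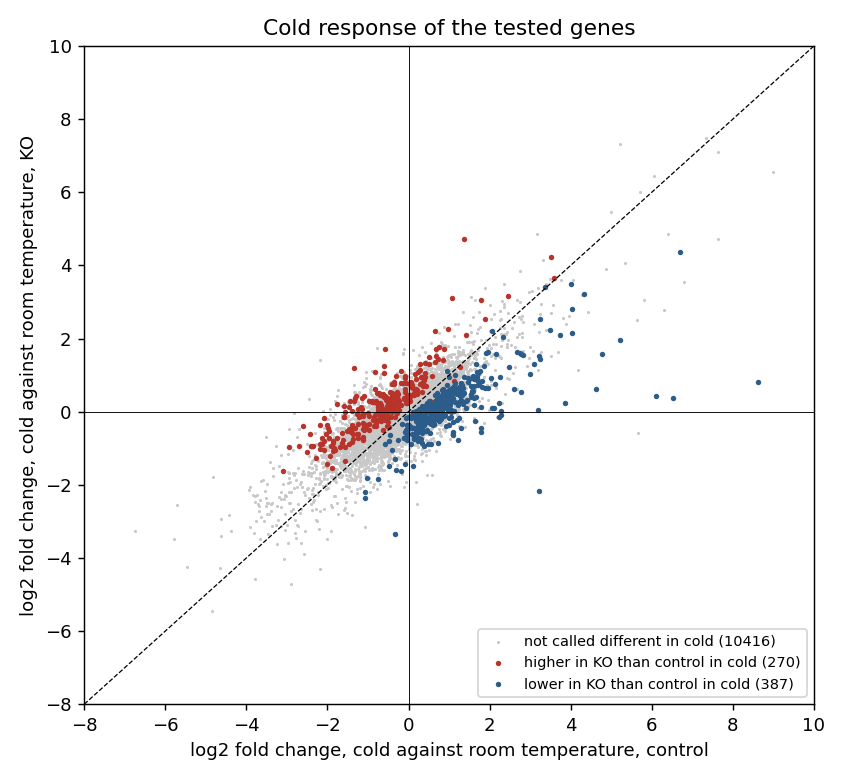
Log2 fold change of cold against RT in control (horizontal axis) and KO (vertical axis), 1 point per gene. Genes higher in KO than control in cold are red (270), lower ones blue (387) and all others grey, and the correlation across all genes is 0.79.

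Whether the response to cold differs between genotypes was tested directly as the difference of both responses, and 2 genes passed with edgeR. Hspa4l, a heat shock protein relative, rose from 113 ± 7.01 CPM to 467 ± 89.8 CPM in control. In KO it was at 95.7 ± 10.6 CPM and 103.1 ± 24.2 CPM (-1.94 ± 0.27, q = 0.0210, but 0.0567 to 0.114 without KO cold 1 or 2, control RT 1 or 2 or KO RT 3). Pcsk6, a proprotein convertase, was at 51.6 ± 5.39 CPM and 177 ± 38.7 CPM in control RT and cold. In KO these were 44.5 ± 2.79 CPM and 48.7 ± 1.99 CPM (-1.65 ± 0.25, q = 0.0269, but 0.0604 to 0.153 without any KO cold library, control RT 1 or 2 or any KO RT library). Neither was called with the replicate block, at -1.86 ± 0.28 (q = 0.0827) and -1.58 ± 0.24 (q = 0.0827), or without the 3 muscle-rich libraries, at -1.99 ± 0.39 (q = 0.417) and -1.59 ± 0.37 (q = 0.457). These folds moved by less than 1 standard error, in fits with fewer residual degrees of freedom, the latter with 1 RT library per genotype. With the muscle score as covariate both were called, at -1.93 ± 0.28 (q = 0.0287) and -1.62 ± 0.25 (q = 0.0394). Genes with the next smallest p, none past the threshold, were Lama4 (1.54 ± 0.26, q = 0.0799, but 0.0232 to 0.0436 without control cold 3 or 4, called with DESeq2), Hk2 (-0.87 ± 0.16, q = 0.108, called with DESeq2) and Arhgap24 (-1.45 ± 0.27, q = 0.108, called with DESeq2). They also included Marcks (0.90 ± 0.17, q = 0.131, called with DESeq2), Fam117a (-1.90 ± 0.37, q = 0.152, but 0.0161 without control cold 4, called with DESeq2) and Slc39a14 (-1.96 ± 0.39, q = 0.152). The others were Sacm1l (-1.25 ± 0.25, q = 0.152, but 0.0295 without control cold 1, called with DESeq2) and Ebf1 (-0.92 ± 0.19, q = 0.155, called with DESeq2). Ucp1 (-0.25 ± 0.19, q = 0.802), Stim1 (0.45 ± 0.22, q = 0.606) and Stim2 (-0.29 ± 0.39, q = 0.897) did not pass, so a difference in their response was not detected here.

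Camera called 4 lists, in each of which 0 members passed, and fry called 0 of 31 (adjusted p = 0.485 for ER chaperones and 0.919 for the other 3). The ER chaperone list was higher, 22 of 24 positive with a median of 0.76 (camera q = 2.68e-09, 0.931 with an estimated correlation), and 9 members were higher in the list alone. Creld2 was at (2.30 ± 0.53, q = 0.232), Pdia6 at (0.99 ± 0.23, q = 0.244, called with DESeq2), Calr at (0.86 ± 0.22, q = 0.255) and Manf at (1.29 ± 0.40, q = 0.377). The extracellular matrix list was lower, 22 of 24 negative (camera q = 0.0102, 0.931 with an estimated correlation). The q was 0.196 to 0.430 without control cold 2 or KO RT 1. In the list alone 0 passed. Its smallest p were those of Col4a2 (-0.74 ± 0.26, q = 0.444), Lox (-0.83 ± 0.33, q = 0.512), Col4a1 (-0.61 ± 0.24, q = 0.520) and Fn1 (-1.03 ± 0.44, q = 0.555). Immediate early and cAMP targets were lower, 17 of 21 negative and 1 lower in the list alone (camera q = 0.0102, 0.931 with an estimated correlation). The q was 0.0923 to 0.6003 without control cold 4, control RT 1 or KO RT 2, and the list turned without control RT 1. Sik1 was at (-2.33 ± 0.63, q = 0.282, called with DESeq2), Dusp1 at (-1.50 ± 0.51, q = 0.439) and Ier3 at (0.94 ± 0.36, q = 0.505). Fos had 0 counts in control RT and is given no fold. Interferon genes were higher, 11 of 13 positive and 0 past the threshold in the list alone (camera q = 0.0478, 0.931 with an estimated correlation). The q was 0.0664 to 0.240 without control cold 1, 2 or 3, KO cold 2, 3 or 4, control RT 2 or KO RT 2 or 3. Ifi27l2a was at (0.69 ± 0.34, q = 0.618), Bst2 at (0.73 ± 0.43, q = 0.702), Ifi44 at (1.16 ± 0.78, q = 0.758) and Xaf1 at (0.75 ± 0.60, q = 0.810).

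An unadjusted p under 0.05 for a different response was met by 913 genes, and DESeq2 called 30, voom 1 and voom with quality weights 1. The count was 0 without KO cold 1 or 2, control RT 1 or 2 or KO RT 3, 1 without KO cold 3 or 4 or KO RT 2, 4 without control cold 1 or 4, and 0 with the replicate block or without the 3 muscle-rich libraries (804 and 720 at unadjusted p under 0.05). Lists numbered 2 without control cold 2 and 11 without control RT 1. In 9 lists, none called, median, mean and camera differed in sign: thermogenic program, calcium cycling, fatty acid oxidation, creatine, adipocyte identity, secreted factors, skeletal muscle, white adipocyte markers and core clock.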

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

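Of the tests in this part, those of other cell types, of the correlation of muscle genes and of the order of muscle scores, and the fits without the muscle-rich libraries or with a muscle covariate, were chosen after the result was seen.

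In both groups of 4 libraries, 430 sets of values, from 213 named genes, the total count and the mitochondrial share, were searched for a library apart from the other 3. A total of 31 was found, against 21.5 by chance at 1 in 20. The value given is the gap to the nearest library as a share of the range in CPM. In control cold, library 2 was high in Cideb (0.837), Xaf1 (0.900), Mfsd12 (0.898) and Fn1 (0.856). Library 3 was low in Sik1 (0.873) and high in Alpl (0.866), Klhdc7a (0.855) and Myh2 (0.858). Library 4 was high in Pdia6 (0.886), Rtp4 (0.838), Gadd45g (0.854) and Fam117a (0.949) and low in Scd1 (0.879) and Cenpa (0.902). In KO cold, library 1 was high in Lrrc52 (1) and Pfkl (0.940) and low in Rtp4 (0.841), Cebpb (0.926) and Mfsd2a (0.913). Library 2 was high in Fgf9 (1), Anxa8 (0.968), Acot1 (0.845) and Fam117a (0.874) and low in Rps6 (0.913), and library 3 was high in Ifit1 (0.933). Library 4 was high in Mcur1 (0.836), Fst (0.845), Coq8a (0.898) and Cebpa (0.922) and low in Lipe (0.837) and Cth (0.937). Fgf9 and Lrrc52 had 1 count each over the KO cold libraries, so their share is 1 by construction.

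The test of a different cold response picked out Hspa4l (difference of log2 fold changes -1.94) and Pcsk6 (-1.65), each lower in KO. Both calls ended with the replicate block (adjusted p = 0.0827 for each) and without the 3 muscle-rich RT libraries (0.417 and 0.457), with log2 values of -1.86 and -1.58, and of -1.99 and -1.59. With the muscle score as covariate both were kept (-1.93 and -1.62, adjusted p = 0.0287 and 0.0394). Among lists it picked out ER chaperones (median difference 0.76), interferon response (0.40), immediate early genes (-0.60) and extracellular matrix (-0.62), none of them with an estimated correlation (adjusted p = 0.931).

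Other splits of the same libraries were refitted. For KO against control in cold, 657 genes stand against at most 1 in the other splits of 35, and only 1 split (the real one) reached the count. For cold against RT in KO, 2090 genes stand against at most 496, again with 1 of 35 splits reaching the count. Every other split mixes libraries of both groups, so a real difference adds to its spread and lowers its count. Both results therefore speak against chance only as far as 1 in 35 allows. For lists in KO against control in cold, 7 stand against at most 13, and 20 of 35 splits gave 7 or more, so chance cannot be excluded for the number of lists.

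The first pattern weighed is the rise of ER chaperone genes in KO cold (median log2 fold change 0.87). With a trend on GC content and length of the transcript end removed, the median was 0.858, against 0.869 before, which argues against that bias. RNA of another cell type would raise its own markers at least as much. Among 8 marker lists with members enough to test the highest median was 0.354, for erythrocytes, and the highest upper quartile 0.563, for white adipocytes, which argues against those types. Lymphocytes, granulocytes with mast cells, and mesothelium with epithelium had 281, 178 and 89 marker counts in cold: pooled, these changed by 0.512 (95% interval -0.307 to 1.33), -0.0600 (-1.08 to 0.963) and 0.261 (-1.03 to 1.56), each including 0.87. RNA of these types and an effect of the loss of the store sensors therefore cannot be told apart here, and both stay open.

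The second pattern is that edgeR called 0 genes at RT (346 at unadjusted p under 0.05; DESeq2 3, both voom fits 0). Smaller groups as the whole cause are argued against: of 24 subsets of 3 KO and 2 control cold libraries, 0 called 10 genes or fewer, with 147 to 536 called. These subsets hold an effect of the size seen in cold. Their median was 221 against 657 with all cold libraries, so smaller groups lower the count, and their part beside a smaller effect stays open. With the muscle score as covariate edgeR also called 0 genes (332 at unadjusted p under 0.05). The covariate adds a coefficient to a comparison of 3 with 2 libraries, so 0 calls cannot decide on muscle RNA as the cause. Without control RT 1, the most muscle-rich library, 3 genes were called (816), and without the 3 muscle-rich libraries 0 (567), so a part played by muscle RNA stays open. The biological coefficient of variation was 16.8% at RT (13% to 19.2% with 1 library left out) and 15.6% in cold (14.5% to 16.6%), so a larger spread cannot be told apart from an equal one. For 200 genes chosen per split in some cold libraries, the median was 0.82 in the others and 0.17 at RT. In 36 of 36 splits RT was under 50%. This choice favours cold, so a smaller effect at RT stays open.

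The third pattern is the high level of skeletal muscle transcripts in control RT 1, KO RT 1 and KO RT 2, at 188, 126 and 78.0 CPM for Ckm and 175.6, 109 and 70.0 CPM for Mylpf, against at most 31.5 and 14.6 CPM in the other libraries. Muscle tissue in the sampled fat and muscle-type expression that brown fat loses in cold were weighed as its sources. Over 13 libraries the 19 muscle genes, 1 of them also in the smooth muscle list, correlated with the mean of the others (median r = 0.973, 0.236 to 0.992), and 2 RT libraries lay below the highest cold score of 4.20. Both values follow from the pattern itself and decide nothing, so the source stays open. Without the 3 libraries, the fold changes of genes called in control were a median of 0.901 of the original, with the same sign for 2741 of 2757. Both fits share control RT 2 and the control cold libraries. Of the 2793 called genes, 2636 had groups apart, which fixes most signs beforehand. The folds thus did not rest on the muscle-rich libraries alone. With a muscle covariate 2012 of the 2793 stayed called. This argues against muscle RNA as the whole basis. A part stays open.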

How the results depend on the processing

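The fits without the 3 muscle-rich RT libraries (control RT 1, KO RT 1 and KO RT 2), with a muscle score as covariate, the exact permutation of list scores and the refits on part of the counts were chosen after the data were seen. Without those 3, control RT 2 and KO RT 3 are the only RT libraries. Lost replication and muscle RNA cannot be told apart as reasons for fewer calls there. For KO against control in cold, the 657 genes were 564 to 982 under other scaling, filters, tools, the replicate block, 2 groups alone and both added muscle fits, 232 at 2-fold or more, and 392 to 716 with 1 library left out, lowest without KO cold 4, 3, 2 and 1 (392, 400, 417 and 425). At RT, edgeR's 0 genes (346 at unadjusted p under 0.05) became 50 with no filter on low counts and 3 with DESeq2, and 0 to 3 with 1 library left out (3 without control RT 1, where 816 had an unadjusted p under 0.05), while all other settings gave 0 (567 at that p without the muscle-rich libraries). In control, cold changed 2793 genes, 1381 at 2-fold or more, 1685 in a fit of 2 groups, 2067 with voom and quality weights, 870 without the muscle-rich libraries and 1067 to 2821 with 1 left out, lowest without control RT 1. In KO these were 2090, 931 at 2-fold or more, 2523 in a fit of 2 groups, 2941 with voom and quality weights, 452 without the muscle-rich libraries, 1304 with the muscle covariate and 1219 to 2271, lowest without KO RT 1. Which genotype had more genes changed in cold therefore depends on the fit: more in KO with 2 groups alone, with quality weights and without control RT 1 (1067 in control, 2234 in KO), more in control in the others. The 2 genes with a different cold response became 133 with no filter, 30 with DESeq2, 1 with voom and with quality weights, and 0 with the replicate block and without the muscle-rich libraries (804 and 720 at unadjusted p under 0.05, against 913). With 1 library left out they numbered 0 (KO cold 1 or 2, control RT 1 or 2, KO RT 3; 723 to 1130 at unadjusted p under 0.05) to 4 (control cold 1 or 4), and 1 without KO cold 3 or 4 or KO RT 2.

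The 7 lists in KO against control in cold became 0 with an estimated correlation, 1 with fry, 0 in the exact permutation of list scores, where the smallest p it can give, 0.0286, adjusts to 0.221, and 4 (without control cold 2) to 9 with 1 library left out. The 5 remaining settings gave 5 to 7. Fewer libraries enter some of these fits, and otherwise the cause was not tested. The replicate block gave 564, 0, 2122, 1629 and 0 genes and 6, 4, 10, 15 and 3 lists in the order of the comparisons, and log2 fold changes did not pair the samples: same-numbered cold libraries correlated at r = -0.16 to 0.14, and 1 of 4 control cold libraries correlated best with its own number.

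Of named genes, these changed sign, and the cause was not tested. Stim2 in KO, cold against RT (0.02, not called), was at -0.0766 with the replicate block and -0.13 to 0.20 with 1 library left out (-0.13, -0.06, -0.000888 and -0.03 without KO cold 2 and 3 and KO RT 1 and 3). At RT, none called, Ucp1 ran from -0.28 to 0.0114 (positive without control RT 2, 0.0048, or KO RT 1, 0.0114), Hspa1a from -3.37 to 1.07, Hspa1b from -2.88 to 1.07 and Hsph1 from -1.98 to 0.70 (positive without control RT 2), and Hbb-bs from -0.0926 to 1.05 (negative without control RT 1). In control, cold against RT, Eno3 ran from -3.87 to 2.16 (on 2 RT counts), Mylpf from -5.33 to a bound of 1.23 and Actn3 from -4.95 to a bound of 0.0558, positive without control RT 1. Both bounds put 3 counts for the 0 of control RT 2, the RT library left, so neither is a measured reversal. Without 1 library, 3526 other values kept sign and side of the threshold, 197 fell short of it and 16 passed it. With the replicate block these were 267, 19 and 2, with DESeq2 255, 10 and 16 (9 had no adjusted p), and with relative log expression scaling 287, 1 and 1. A fold over a group at 0 counts entered as a bound from 3 counts (59 values), and Fos, at 0 in control RT, had no value for a different response. Where 1 library is left in a group, it is assumed to vary like the others. In simulated KO against control in cold at the real library sizes, 21.8% of genes changed 1.5-fold were found. With each count kept at a chance of 50%, fewer genes were called in 3 comparisons in each of 5 draws: 385 to 423 against 657 for KO in cold, 1888 to 1946 against 2793 for cold in control and 1421 to 1453 against 2090 for cold in KO, so depth limits these counts. EdgeR called 0 genes at RT in each draw (309 to 333 at unadjusted p under 0.05), and 0 to 4 with a different cold response (669 to 724).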

Other observations

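Of the tests in this part, the exact permutation of list scores and the comparison of overlaps between split control libraries were chosen after the data were seen.

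Core clock genes changed in cold in both genotypes without a shared direction. In control, of 19 genes, 7 rose, 6 fell and 6 did not pass (list alone, 10 higher and 6 lower), with camera q = 0.456, and in KO 8 rose and 5 fell (camera q = 0.169). Cry1 (2.28 ± 0.30, q = 8.09e-05) and Nfil3 (2.80 ± 0.45, q = 0.000364) rose in control, and Nr1d1 (-2.58 ± 0.43, q = 0.000476) and Per3 (-2.39 ± 0.42, q = 0.000829, but 0.0678 without control RT 1, -1.43 without control RT 1) fell. The hour of sampling is not in the labels. In lipid uptake, of 17 genes, 5 rose, 2 fell and 10 did not pass (list alone, 5 higher and 2 lower) in control, with camera q = 0.687, and 5 rose and 1 fell in KO (camera q = 0.214). Lpl (1.11 ± 0.11, q = 7.17e-06), Lipg (2.46 ± 0.41, q = 0.000489) and Gpihbp1 (1.08 ± 0.21, q = 0.00149, but 0.0511 without control RT 1, 0.72 without control RT 1) rose in control, and Scarb1 fell (-1.83 ± 0.21, q = 2.68e-05).

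Genes raised by cold in control were often lower in KO cold: 260 were both (49.0 for independent lists), and 128 were lower in cold and higher in KO cold (33.9), while 11 rose in both and 6 fell in both (34.2 and 48.7). Both comparisons use the control cold libraries, which alone gave r = -0.42 across genes in 30 simulations without any effect, against -0.48 measured. The covariance was -0.0399 in the simulations and -0.197 measured, and 0.0333 genes on average were called in both, since those simulations held no effect to call. With the control cold libraries split between both comparisons in 6 ways, 86 to 163 genes were raised by cold and lower in KO (10.9 to 44.0 for independent lists), 20 to 48 were the reverse (4.43 to 24.7), and r was -0.42 to -0.17. Those raised in both numbered 0 to 42 (5.08 to 26.4), above the independent value in 1 split (42 against 26.4) and below it in 5, and those lower in both 0 to 25 (9.48 to 41.2), below it in 6.

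Scored per library, 4 of 31 lists separated KO from control cold without overlap: ER chaperones, heat shock and proteasome, immediate early genes and lipid uptake. Each had an exact permutation p = 0.0286, the smallest that 70 splits can give, and adjusted p = 0.221.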
